A study of Arabidopsis thaliana with 12 samples.

How the data were processed

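The values analysed were the deposited FPKM values of 12 libraries and 33557 genes, and the series table held the same values as the files per library (largest difference 0). Per the submitters' processing notes, reads were handled with Trim Galore, STAR 2.5.4, HTSeq 0.6.0 and edgeR on TAIR10, with no role or order given for these tools. The formula of the scaling and the annotation version are not stated there. Per the labels, libraries were stranded messenger RNA libraries read at 50 bases from a single end.

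The plan written before the data were examined used a count-based test. The deposited values are FPKM, so that test was replaced by limma on log2(FPKM + 1), and DESeq2 was not run. Within a gene the values of a library are whole multiples of a step, and this step was recovered for 14925 of 22373 genes with enough values (66.7%), within 0.05 reads and up to 3000 reads. A relation of the step to length was sought in 3089 genes with a single long exon. The most frequent ratio, of a step inverse to the exon length minus 204 bases, held for 465 of these, a minority. A step can be a multiple of the true one, so estimated reads are approximate. Reads were estimated for 31422 genes, from the recovered step or, without one, from this length relation. Sizes of libraries in reads rest on that relation, while ratios between libraries of the value of a read do not. They gave 12.61 to 15.68 M reads in genes per library and a library size behind the scaling of 6.23 to 17.0 M. The FPKM of 1 read in a gene of 1500 bases was 0.0454 to 0.1238, and 30.9% to 36.5% of genes were listed at 0. Genes of the organelles took 0.68% to 1.55% of the FPKM sum. None of 6 housekeeping genes had a value of 0. Replicates had a Pearson r of 0.9865 to 0.9898 on the log scale, and their chi-square over degrees of freedom, 1.91 to 5.15, lay above counting error.

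Genes were tested with at least 1 FPKM in at least 2 libraries and at least 10 estimated reads in at least 2 libraries, which left 19777. The fit had 1 coefficient per group over all 12 libraries, precision weights from voom on the estimated reads, and robust moderated variances, with 6 residual and a median of 4.82 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each comparison, and genes under adjusted p 0.05 were called. The weights and the minimum of reads were chosen among several settings on simulated data before any comparison of the real groups was fitted. In 5 simulated sets with 200 changed genes each, set up like the comparison at 6 h, the chosen test found 21.7%, 69.9%, 90.7% and 95.2% of changes of 1.5, 2, 4 and 8 fold. False calls were 2.7% of all calls, against 11.9% without weights and 6.5% with voom on the estimated reads, and 0 signs were wrong. The other tests found more of the changes of 2 fold and above: they found 19.7%, 78.7%, 97.6% and 99.2% without weights and 28.9%, 80.3%, 98.8% and 100% with voom. The chosen test gave fewer false calls at the price of missed changes. The settings were chosen on the same kind of simulation that gives these rates, so the rate of false calls may be somewhat low. In the real comparison at 6 h 73.4% of genes were called, far more than were changed in the simulated sets. Both kinds of rate depend on the share of changed genes and on the spread. They therefore do not carry over to the real comparisons.

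Lists were written before the data were examined: 28 lists of named genes with 503 distinct members, of which 475 were paired by the reference and 28 are shown under the name the reference gives, and 12 families taken from gene descriptions, 40 in all. They were tested with camera at its preset correlation of 0.01, with p-values adjusted over the 40, and again with a correlation estimated from the residuals. Names and descriptions came from the NCBI annotation of TAIR10.1, which named 32810 of the genes in the files and left 747 unnamed. Its exon coordinates gave the exon lengths used to estimate reads and the exon sequences compared below. The submitters state no annotation version, so these lengths may differ from those behind the FPKM values.

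Named genes followed a rule written before the data were examined. For each comparison of As(V) with mock these were the 5 highest and 5 lowest changes among called genes with no overlap between libraries. A mean of at least 5 FPKM over all libraries of the groups compared was required. Under the same minimum, up to 3 of the largest changes were added per list with at least 3 called genes. There were also 10 fixed genes: GL2, ANL2, AT2G21045 (HAC1), ASK18, WRKY6, PHT1;1, PHT1;4, SPX1, AT5G44070 (PCS1) and GSH1. The rule was written for scaled counts and was applied to FPKM. For other comparisons it took the 3 highest and 3 lowest. A few other members of lists are named beyond the rule. For 266 genes the exon sequence was searched for in the reference genome in windows of 50 bases. In 7 genes over 20% of the windows also occurred elsewhere in the genome.

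Alternatives tried were median-of-ratios scaling and library totals from the estimated reads, no filter, a minimum of 5 FPKM, only the libraries compared, a replicate term, removal of organelle genes, limma-trend without weights, a minimum log2 change of 1, and leaving out each library in turn. Those added after the data were seen were voom on the estimated reads, pseudocounts of 0.1 and 5 FPKM, no minimum of reads, and a fit without the libraries of 6 h. Left out of the tests were 739 genes past the FPKM minimum, 221 because no reads could be estimated and 518 because they lay under the minimum of reads. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.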

Results

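Root messenger RNA was measured in Arabidopsis thaliana Col-0 seedlings that met arsenate, As(V), a chemical analogue of phosphate taken up by phosphate transporters. Seedlings grew for 7 days with 1 mM phosphate and for 2 days without it, and their roots were then kept in phosphate-free liquid medium with 30 µM As(V), or without As(V) (mock), for 1.5, 6 or 24 h. The 12 libraries form 6 groups of 2 replicates, each from 60 seedlings. Between 12.61 and 15.68 M reads per library fell in genes, as estimated from the deposited FPKM values, and 1 read in a gene of 1500 bases was worth 0.0454 to 0.1238 FPKM. From 17691 to 19138 genes per library reached 1 FPKM. The labels do not say whether replicates were separate cultures, so the p-values below measure only the spread between these samples. Levels are means ± SD over 2 libraries, and changes are log2 fold changes of FPKM + 1 with their SE, a scale that understates changes of genes near 0. All gene p-values come from limma with Benjamini-Hochberg adjustment over 19777 genes, and gene lists were tested with camera.

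The As(V) libraries differed from mock in how their values were scaled. The library size behind the deposited values was 0.639 and 0.654 of the reads in genes at 1.5 h of As(V), 0.444 and 0.459 at 6 h, and 1.122 and 1.061 at 24 h, against 0.994 to 1.049 in mock. The 50 genes with the most reads took 17.1% and 16.7% of reads at 1.5 h of As(V), against 11.5% and 11.8% in mock, and at least as large a share at 6 h. As deposited, the median change of all genes was -0.09 at 1.5 h, -0.12 at 6 h and -0.06 at 24 h. With library totals alone it was -0.61, -1.04 and 0.03, so directions are relative to the deposited scaling. With median-of-ratios scaling it was -0.03, -0.04 and 0.03. That scaling gave 6455 genes higher and 6152 lower at 1.5 h, and 7518 and 6839 at 6 h. No call made as deposited was reversed by it at these times. Both scalings leave the median change near 0, so this does not decide between them and library totals. Each list reported in full below whose median changes sign with library totals is given with both values.

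The first comparison asked which genes responded within 1.5 h of As(V). Small heat shock proteins, chaperones that bind unfolding proteins, rose most: AT1G53540 went from 9.10 ± 4.23 to 8360 ± 179 FPKM, a change of 9.76 ± 0.40 (adjusted p = 2.1e-08), and HSP17.6A from 13.2 ± 5.16 to 8640 ± 28.4 FPKM. AT5G44070, the phytochelatin synthase PCS1 whose peptide products bind arsenic, rose from 34.8 ± 0.526 to 398 ± 35.4 FPKM, by 3.48 ± 0.13 (adjusted p = 1.5e-09). Flavonoid genes fell, with FLS1 at 58.1 ± 7.04 FPKM against 1110 ± 10 in mock. GL2, the homeodomain factor that specifies non-hair cells of the root epidermis, fell from 6.10 ± 0.714 to 1.78 ± 0.447 FPKM, by -1.36 ± 0.16 (adjusted p = 1.9e-05).

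At 1.5 h 5960 genes were higher and 6679 lower with As(V), or 63.9% of those tested. With library totals alone the split was 3057 higher and 12309 lower (19.9% higher, against 47.2%), and 919 of the genes called higher were then called lower. The 5 highest at 1.5 h were AT1G52560 at 10.03 ± 0.56, AT1G53540 at 9.76 ± 0.40, ATHSP22.0 at 9.69 ± 0.45, Hsp70b at 9.31 ± 0.23 and HSP17.6A at 9.30 ± 0.38. All are annotated as heat shock proteins or HSP20-like chaperones, and mock levels were 1.52 ± 0.898 FPKM for AT1G52560, 3.14 ± 1.58 for ATHSP22.0 and 5.86 ± 1.42 for Hsp70b. The 5 lowest were the glyoxal oxidase-related gene AT1G19900 at -5.45 ± 0.27, the flavonoid hydroxylase TT7 at -5.06 ± 0.30, UGT84A1 at -4.82 ± 0.33, the peroxidase AT2G39040 at -4.80 ± 0.42 and XTH13 at -4.63 ± 0.57. Their adjusted p-values ran from 1.5e-08 for AT1G19900 to 2.9e-05 for XTH13.

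**Figure D1:**
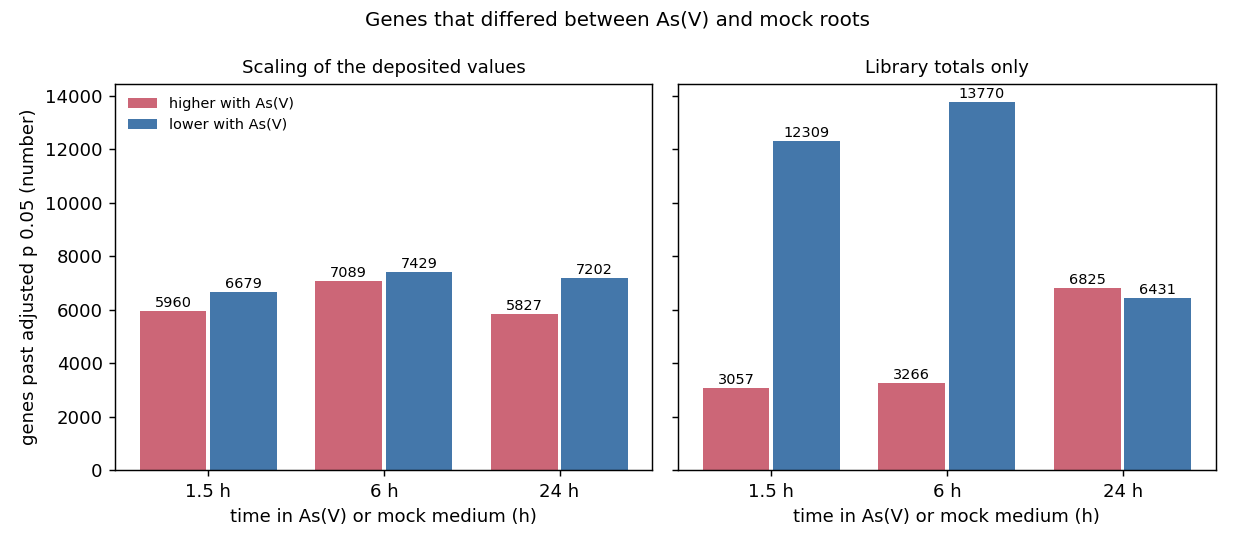
Number of genes past adjusted p 0.05 (limma) that were higher or lower with As(V) than in mock at 1.5, 6 and 24 h, with the scaling of the deposited values (left) and with library totals only (right). At 6 h 7089 genes were higher and 7429 lower as deposited, against 3266 and 13770 with library totals.

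Genes of arsenic handling split at 1.5 h. ASK18, an E3 ligase subunit, rose from 11.6 ± 1.12 to 292 ± 2.63 FPKM (4.54 ± 0.11, adjusted p = 9.1e-11), and WRKY6, a repressor of phosphate transporter genes under arsenate, from 39.9 ± 2.95 to 364 ± 24.6 FPKM (3.16 ± 0.14, adjusted p = 6.3e-09). GSH1, which makes the first intermediate of glutathione, rose by 0.99 ± 0.05 (adjusted p = 1.4e-08). The phosphate transporters PHT1;1 and PHT1;4 changed by -1.71 ± 0.09 and -1.89 ± 0.14, and SPX1, a sensor of phosphate status, by -0.55 ± 0.09 (adjusted p = 2.7e-08, 4.3e-07 and 0.00034). Of the exon sequence windows of PHT1;1, 42.5% also occur elsewhere in the genome, so its level is uncertain. AT2G21045, the arsenate reductase HAC1, was not called (0.11 ± 0.06, adjusted p = 0.16) and lay at -0.52 with library totals (adjusted p = 3.2e-06). ANL2, a homeodomain factor of the same class as GL2, had a change of -0.24 ± 0.09 (adjusted p = 0.042), a call lost in 8 of 17 alternatives.

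Several stress and detoxification lists rose at 1.5 h. Of 30 heat shock proteins and factors, 30 rose, and 30 adjusted over the list alone, with a median of 6.88 (camera, adjusted p = 4.5e-19, and adjusted p = 0.22 with an estimated correlation). Among 16 xenobiotic detoxification genes 13 rose and 3 were not called (13 adjusted over the list alone, adjusted p = 2.4e-07, and adjusted p = 0.22 with an estimated correlation), led by the cytochrome P450 genes CYP81D8 at 8.46 ± 0.50 and CYP81D11 at 6.24 ± 0.21. The sulfate assimilation and glutathione list had 22 genes higher, 3 lower and 6 not called of 31 (22 and 3 adjusted over the list alone, adjusted p = 3.8e-06, and adjusted p = 0.22 with an estimated correlation). With library totals 17 were higher and 11 lower, and the median of 1.35 became 0.73. LSU1 rose by 6.88 ± 0.69, SHM7 by 5.35 ± 0.18 and APS3 by 5.22 ± 0.16. All 9 mitochondrial stress genes rose (9 adjusted over the list alone, adjusted p = 5.4e-06, and adjusted p = 0.22 with an estimated correlation), including the alternative oxidase AOX1A, from 32.2 ± 5.40 to 570 ± 18.1 FPKM. WRKY factors had 31 higher, 10 lower and 17 not called of 58 (31 and 10 adjusted over the list alone, adjusted p = 0.0029, and adjusted p = 0.39 with an estimated correlation). WRKY33 rose by 5.29 ± 0.32 and WRKY75 by 4.33 ± 0.22, and the list's median of 0.52 became -0.03 with library totals. Reactive oxygen scavenging genes, 10 higher, 4 lower and 3 not called of 17 (10 and 4 adjusted over the list alone), did not pass (adjusted p = 0.076), and their median of 0.32 became -0.31 with library totals, with 7 higher and 10 lower. Ethylene genes, 9 higher, 5 lower and 1 not called of 15 (9 and 5 adjusted over the list alone), did not pass as a list (adjusted p = 0.33), although ACS7, an enzyme of ethylene synthesis, rose by 5.26 ± 0.20 and ERF6 by 5.87 ± 0.27.

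Unfolded protein response genes had 5 higher, 8 lower and 3 not called of 16 (5 and 8 adjusted over the list alone), with a median of -0.30, a mean of 0.65 and a test pointing down (camera, adjusted p = 0.88). Within it TIN1 rose by 5.48 ± 0.12 and BZIP60 by 2.92 ± 0.15. ERF and AP2 factors had 23 higher, 20 lower and 22 not called of 65 (24 and 20 adjusted over the list alone, adjusted p = 0.51), with a median of -0.04, 0.02 with median-of-ratios scaling and -0.47 with library totals, and a mean of 0.51; AT1G71520 rose by 7.90 ± 0.46. Camalexin and indole genes, which make defence compounds, had 5 higher, 3 lower and 4 not called of 12 (5 and 3 adjusted over the list alone, adjusted p = 0.27). GGP1 rose by 2.71 ± 0.10. The 6 genes of the root cap and stem cell niche held 1 higher, WOX5 at 0.54 (adjusted p = 0.042), and 1 lower, BRN1 at -0.79 (adjusted p = 0.021), both outside the rule for named genes, with 4 not called and 0 called adjusted over the list alone (camera, adjusted p = 0.74).

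Several growth and cell wall lists fell at 1.5 h. Of 11 phenylpropanoid and flavonoid genes, which make ultraviolet screens and lignin precursors, 10 fell and 1 was not called (10 adjusted over the list alone), with a median of -1.85 (camera, adjusted p = 3e-05, and adjusted p = 0.22 with an estimated correlation). Besides TT7, AT3G55120, a chalcone isomerase, changed by -4.57 ± 0.26 and FLS1 by -4.24 ± 0.23. Auxin genes had 2 higher, 14 lower and 2 not called of 18 (2 and 14 adjusted over the list alone, adjusted p = 0.0016, and adjusted p = 0.22 with an estimated correlation). The transporter genes PIN7 and LAX3 changed by -2.45 ± 0.15 and -2.15 ± 0.12. Expansins, which loosen cell walls, had 3 higher, 16 lower and 3 not called of 22 (3 and 16 adjusted over the list alone, adjusted p = 0.0072, and adjusted p = 0.22 with an estimated correlation). The list did not pass with library totals (adjusted p = 0.17). EXPA7 changed by -3.39 ± 0.28 and EXPA12 by -3.02 ± 0.56. Leucine-rich repeat receptor kinases had 25 higher, 85 lower and 28 not called of 138 (25 and 86 adjusted over the list alone, adjusted p = 0.0002, and adjusted p = 0.22 with an estimated correlation), BAM3 falling by -3.09 ± 0.18. UDP-glycosyltransferases had 24 higher, 51 lower and 24 not called of 99 (26 and 53 adjusted over the list alone, adjusted p = 0.087). UGT73B5 rose by 5.28 ± 0.16, whereas UGT84A1 was among the 5 lowest. Cell cycle and DNA replication genes, with 4 higher, 11 lower and 8 not called of 23 (4 and 11 adjusted over the list alone), did not pass, nor did xyloglucan endotransglucosylases, with 8 higher, 13 lower and 2 not called of 23 (8 and 13 adjusted over the list alone, adjusted p = 0.15 and 0.27). With library totals 0 of the cell cycle and DNA replication genes were higher and 19 lower, and their median of -0.38 became -0.92. In all 19 of 40 lists passed at 1.5 h with the preset correlation and 0 with an estimated correlation, where camera gave 4 lists an unadjusted p under 0.05.

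The comparison at 6 h asked how far the response had moved. The glutathione transferase GSTU24, of the enzymes that attach glutathione to toxic compounds, rose from 16.7 ± 1.28 to 6530 ± 726 FPKM, a change of 8.53 ± 0.16 (adjusted p = 7.7e-12). The vacuolar transporters ABCC2 and ABCC3, of the class that moves phytochelatin complexes into the vacuole, rose by 4.13 ± 0.08 and 5.37 ± 0.12. Casparian strip genes of the endodermis fell, with PER64 at 1.6 ± 0.0484 FPKM against 60.2 ± 1.07 in mock. GL2 fell from 9.30 ± 0.513 to 2.94 ± 0.109 FPKM (-1.39 ± 0.14, adjusted p = 3.5e-06), while ANL2 rose from 11.1 ± 0.636 to 31.8 ± 1.66 FPKM (1.45 ± 0.08, adjusted p = 1.4e-08). With library totals the median change of all genes at 6 h was -1.04, against -0.12 as deposited. The sizes of changes at 6 h therefore depend on the scaling. At 6 h the ratio of scaling size to reads in genes lay at -1.21 (log2, As(V) minus mock). Most of the ANL2 rise of 1.45 may thus rest on the deposited scaling.

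At 6 h 7089 genes were higher and 7429 lower, or 73.4% of those tested. With library totals alone 3266 were higher and 13770 lower (19.2% higher, against 48.8%), and 2292 of the genes called higher were then called lower. The 5 highest changes were AT5G64401 at 10.41 ± 0.84, AT1G53540 at 10.19 ± 0.40, HSP18.2 at 10.10 ± 0.32, UGT74E2 at 9.96 ± 0.49 and HSP17.6A at 9.90 ± 0.39 (largest adjusted p = 4.9e-07). AT5G64401, an uncharacterized gene, was at 3390 ± 672 FPKM with As(V) and 2.57 ± 3.64 in mock at 6 h, but at 46.7 ± 0.116 in mock at 1.5 h. The lowest 5 included XTH31 at -7.26 ± 0.31, the peroxidase AT1G34510 at -6.02 ± 0.62 and AT5G04960 at -5.82 ± 0.35. The lipid-transfer protein gene AT1G48750 and AT1G68238 completed them, listed at 0 in both As(V) libraries and at 101 ± 0.272 and 62.9 ± 4.05 FPKM in mock, so no fold is given.

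Among the arsenic genes ASK18 rose by 5.27 ± 0.10, WRKY6 by 3.5 ± 0.14 and GSH1 by 1.84 ± 0.05 at 6 h (adjusted p = 7.7e-12, 9.5e-10 and 3.6e-11). The sizes of these rises depend on the scaling as well. AT2G21045 (HAC1) rose from 244 ± 3.57 to 583 ± 25.2 FPKM (1.25 ± 0.06) and AT5G44070 (PCS1) from 48.7 ± 2.47 to 121 ± 4.18 (1.3 ± 0.13), calls that were both lost with library totals (0.04 and 0.10). PHT1;1 changed by -1.46 ± 0.09, PHT1;4 by -3.37 ± 0.19 and SPX1 by -2.91 ± 0.11 (adjusted p = 5.8e-08, 2.2e-08 and 5.1e-10). The arsenic transport and reduction list as a whole had 6 higher, 6 lower and 4 not called of 16 (6 and 6 adjusted over the list alone), with a median of -0.25, a mean of 0.65 and a test pointing up (camera, adjusted p = 0.81). With library totals 5 were higher and 10 lower, and the median was -1.34.

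**Figure D2:**
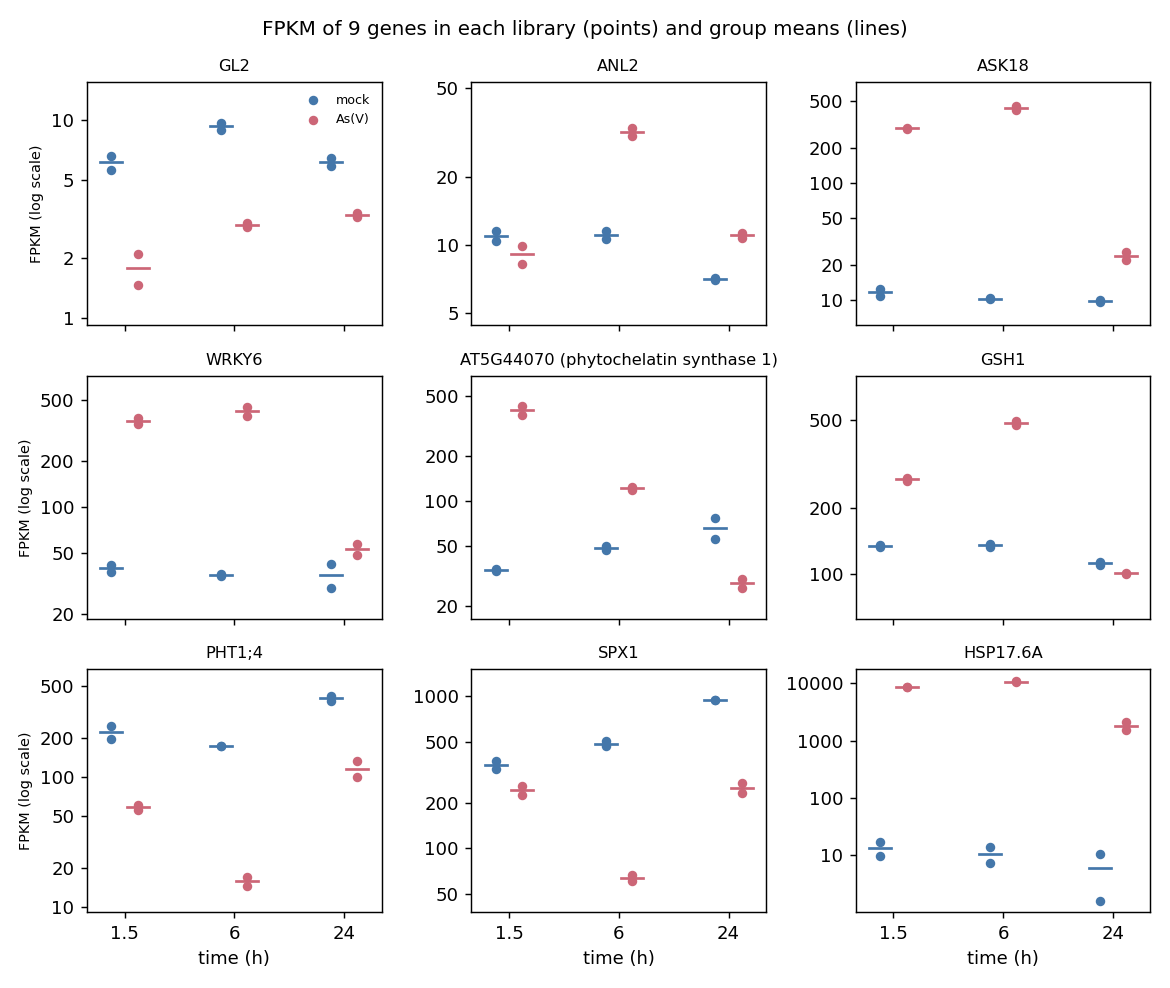
FPKM on a log axis of 9 genes in each library (points) at 1.5, 6 and 24 h, mock in blue and As(V) in red, with lines at the means of 2 libraries. GL2 was lower with As(V) at every time, at 1.78, 2.94 and 3.32 FPKM against 6.10, 9.30 and 6.15, and ASK18 went from 436 FPKM at 6 h to 23.8 at 24 h.

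Root cell type lists bear on the epidermal differentiation that the study concerns. Most root hair genes were lower at every time. At 1.5 h 25 of 33 fell and 3 rose, with a median of -1.09, and at 24 h 26 fell and 2 rose, with a median of -1.14 (camera, adjusted p = 9.4e-06 and 6.6e-07, and adjusted p = 0.22 and 0.11 with an estimated correlation). At 6 h 9 rose, 23 fell and 1 was not called (9 and 23 adjusted over the list alone), with a median of -1.71 (camera, adjusted p = 0.0026, and adjusted p = 0.29 with an estimated correlation). The cell wall protein genes PRP1 and PRP3 changed by -4.43 ± 0.25 and -3.79 ± 0.14, and EXPA18 by -3.58 ± 0.23. Epidermal patterning genes had 5 higher, 7 lower and 5 not called of 17 (5 and 7 adjusted over the list alone) and did not pass as a list (adjusted p = 0.62). With library totals 1 was higher and 14 lower, and the median of -0.35 became -1.41. ETC3, an inhibitor of non-hair fate, and the receptor kinase SCM changed by -2.43 ± 0.52 and -2.13 ± 0.20. Endodermis and Casparian strip genes had 9 lower and 1 not called of 10 (9 adjusted over the list alone, adjusted p = 0.0015, and adjusted p = 0.33 with an estimated correlation). CASP4 changed by -5.08 ± 0.92. Aquaporins, the water channels, had 3 higher, 14 lower and 1 not called of 18 (3 and 14 adjusted over the list alone, adjusted p = 0.0027, and adjusted p = 0.34 with an estimated correlation). TIP2;2 changed by -3.94 ± 0.16 and TIP2;1 by -3.66 ± 0.12. Cell cycle and DNA replication genes had 3 higher, 19 lower and 1 not called of 23 (3 and 19 adjusted over the list alone, adjusted p = 0.0062, and adjusted p = 0.56 with an estimated correlation), with CYCB1;4, a mitotic cyclin, at -2.44 ± 0.25, and the list did not pass with library totals (adjusted p = 0.074).

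Proteasome subunits, which degrade ubiquitin-tagged proteins, already passed at 1.5 h, with 37 higher and 3 lower of 44 (37 and 3 adjusted over the list alone, camera, adjusted p = 1.5e-06, and adjusted p = 0.22 with an estimated correlation) and a median of 0.44. With library totals the list did not pass at 1.5 h (adjusted p = 0.14), with 9 higher and 22 lower and a median of -0.18. At 6 h they had 36 higher, 4 lower and 4 not called of 44 (38 and 4 adjusted over the list alone, camera, adjusted p = 4.1e-07, and adjusted p = 0.29 with an estimated correlation), RPT3 rising from 137 ± 4.13 to 2090 ± 19.4 FPKM, and with library totals 14 were higher and 24 lower and their median of 1.00 became -0.20. Glutathione transferases had 20 higher, 4 lower and 3 not called of 27 (20 and 5 adjusted over the list alone, adjusted p = 0.0011, and adjusted p = 0.29 with an estimated correlation). With library totals 17 were higher and 8 lower. GSTU25 rose by 5.55 ± 0.21 after GSTU24. Circadian clock genes had 8 higher, 2 lower and 3 not called of 13 (8 and 2 adjusted over the list alone, adjusted p = 0.034, and adjusted p = 0.34 with an estimated correlation), the morning gene CCA1 rising from 0.314 ± 0.0184 to 70.7 ± 10.2 FPKM and PRR7 from 3.22 ± 0.186 to 151 ± 1.56. NAC factors had 29 higher, 16 lower and 15 not called of 60 (29 and 17 adjusted over the list alone, adjusted p = 0.048, and adjusted p = 0.33 with an estimated correlation). ANAC102 rose by 5.15 ± 0.12. With library totals 23 NAC factors were higher and 27 lower, and the list's median of 0.38 became -0.24. Reactive oxygen scavenging genes had 11 higher, 4 lower and 2 not called of 17 (11 and 4 adjusted over the list alone, adjusted p = 0.038, and adjusted p = 0.29 with an estimated correlation). APX2 rose by 8.49 ± 0.45 and CAT1 by 3.27 ± 0.11. The list did not pass with library totals (camera, adjusted p = 0.35), where 5 were higher and 9 lower and its median of 0.85 became -0.34. Abscisic acid genes, 6 higher, 1 lower and 3 not called of 10 (6 and 1 adjusted over the list alone), had a median of 1.37 without passing (adjusted p = 0.051), 5 being higher and 4 lower with library totals, and the phosphatase gene HAB1 rose by 3.89 ± 0.11. In all 23 of 40 lists passed at 6 h with the preset correlation and 0 with an estimated correlation, where camera gave 4 an unadjusted p under 0.05.

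**Figure D3:**
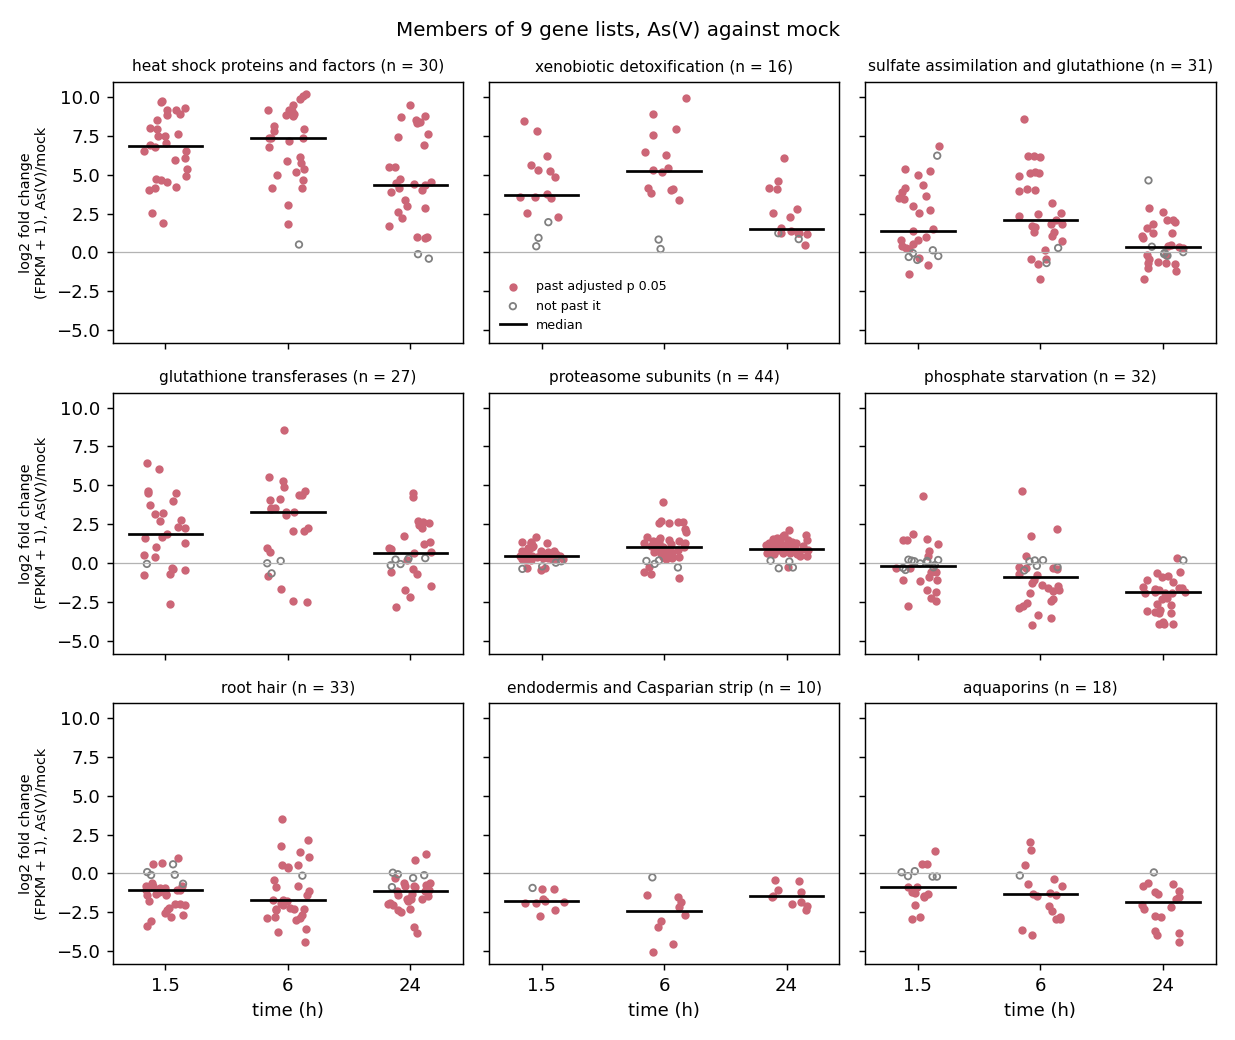
Log2 fold changes (FPKM + 1, As(V) over mock, vertical axis) of the measured members of 9 gene lists at 1.5, 6 and 24 h, with filled points past adjusted p 0.05 (limma), open points not past it, and lines at the median. Heat shock medians were 6.88, 7.37 and 4.35 and phosphate starvation medians -0.21, -0.94 and -1.90. With library totals they became 6.25, 6.16 and 4.46 and -0.71, -2.10 and -1.81 in the same order. The rise of the heat shock median from 1.5 to 6 h and the fall of the phosphate starvation median from 6 to 24 h were thus lost, and the proteasome medians at 1.5 and 6 h became -0.18 and -0.20.

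The comparison at 24 h asked what remained after a day, with the phosphate starvation response among the lists. IPS1, a noncoding RNA induced when phosphate is scarce, was at 99.8 ± 8.20 FPKM with As(V) and 1560 ± 69.3 in mock, a change of -3.95 ± 0.11 (adjusted p = 1.9e-09), and SPX3 changed by -3.90 ± 0.11. The iron uptake genes IRT1 and FRO2 changed by -3.79 ± 0.28 and -4.30 ± 0.41. Small heat shock proteins were still higher, HSP18.2 at 4710 ± 1310 FPKM against 5.68 ± 2.48. GL2 fell from 6.15 ± 0.425 to 3.32 ± 0.105 FPKM (-0.73 ± 0.10, adjusted p = 8.9e-05).

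At 24 h 5827 genes were higher and 7202 lower, or 65.9% of those tested, and with library totals 6825 and 6431. The highest 5 changes were HSP18.2 at 9.49 ± 0.39, HSP17.4 at 8.78 ± 0.50, AT1G53540 at 8.75 ± 0.56, ATHSP22.0 at 8.5 ± 0.78 and HSP17.6A at 8.37 ± 0.57 (largest adjusted p = 5.1e-06). The lowest included the pectin lyase-like gene AT5G14650 at -5.88 ± 0.79 and the peroxidase AT5G15180 at -5.38 ± 0.20 (adjusted p = 0.00011 and 7.7e-09). The others were 3 related lipid-transfer protein genes, AT4G12520 at -5.60 ± 0.73, AT5G46900 at -5.59 ± 0.86, and AT4G12510, listed at 0 with As(V) and at 38.8 ± 1.75 FPKM in mock. Of their exon sequence windows 58.1%, 22.5% and 51.8% also occur elsewhere in the genome, so the level of each is uncertain.

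Several arsenic genes had changed sides or sizes by 24 h. AT5G44070 (PCS1) was lower with As(V), at 28.4 ± 2.94 against 66.6 ± 14.7 FPKM (-1.19 ± 0.13, adjusted p = 1.2e-05), and AT2G21045 (HAC1) too (-0.33 ± 0.06, adjusted p = 0.00067). GSH1 had a change of -0.16 ± 0.05 (adjusted p = 0.015), a call lost in 5 of 17 alternatives. ASK18, WRKY6 and ANL2 were higher by 1.19 ± 0.12, 0.56 ± 0.14 and 0.58 ± 0.09 (adjusted p = 5.6e-06, 0.0048 and 0.00012). PHT1;1 changed by -0.63 ± 0.09, PHT1;4 by -1.81 ± 0.13 and SPX1 by -1.91 ± 0.09 (adjusted p = 7.9e-05, 4.9e-07 and 2.6e-08).

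Nutrient and barrier lists fell at 24 h. Of 32 phosphate starvation genes 30 fell, 1 rose and 1 was not called (30 and 1 adjusted over the list alone), with a median of -1.90 (camera, adjusted p = 5.6e-12, and adjusted p = 0.12 with an estimated correlation). Nitrate uptake and assimilation genes had 2 higher and 13 lower of 15 (2 and 13 adjusted over the list alone, adjusted p = 0.001, and adjusted p = 0.12 with an estimated correlation). AT1G13300 changed by -3.41 ± 0.19 and the nitrate reductase NIA1 by -2.51 ± 0.11. Iron deficiency and homeostasis genes had 4 higher, 14 lower and 6 not called of 24 (4 and 14 adjusted over the list alone) and did not pass as a list (adjusted p = 0.32). Suberin genes, which make the waxy barrier of the endodermis, had 11 lower and 1 not called of 12 (11 adjusted over the list alone, adjusted p = 2.8e-05, and adjusted p = 0.26 with an estimated correlation). CYP86A1 changed by -2.42 ± 0.14 and ABCG6 by -2.40 ± 0.16. Xylem and phloem genes had 7 lower and 2 not called of 9 (7 adjusted over the list alone, adjusted p = 0.0013, and adjusted p = 0.17 with an estimated correlation). XCP2 changed by -1.57 ± 0.06. Photosynthesis genes of green tissue had 7 lower and 7 not called of 14 (7 adjusted over the list alone, adjusted p = 0.12), PSAF falling from 21.4 ± 0.387 to 5.32 ± 0.181 FPKM.

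Several cell wall families fell at 24 h as well, but expansins, with 5 higher, 12 lower and 5 not called of 22 (5 and 12 adjusted over the list alone), did not pass (adjusted p = 0.14). Class III peroxidases, which cross-link wall polymers, had 3 higher, 48 lower and 6 not called of 57 (3 and 48 adjusted over the list alone, camera, adjusted p = 3.7e-10, and adjusted p = 0.1 with an estimated correlation). Extensins had 1 higher, 30 lower and 7 not called of 38 (1 and 30 adjusted over the list alone, adjusted p = 2.1e-08, and adjusted p = 0.1 with an estimated correlation). EXT13 changed by -3.48 ± 0.10 and ELP by -3.10 ± 0.10. Xyloglucan endotransglucosylases had 2 higher, 19 lower and 2 not called of 23 (2 and 19 adjusted over the list alone, adjusted p = 2e-05, and adjusted p = 0.1 with an estimated correlation). XTH26 changed by -4.75 ± 0.31 and XTH17 by -4.34 ± 0.26. Cytochromes P450 had 17 higher, 78 lower and 38 not called of 133 (17 and 78 adjusted over the list alone, adjusted p = 5.9e-05, and adjusted p = 0.1 with an estimated correlation). CYP708A2 changed by -4.29 ± 0.30. Jasmonate genes had 9 lower and 10 not called of 19 (9 adjusted over the list alone, adjusted p = 0.066). VSP1 changed by -3.22 ± 0.47 and MYC2 by -1.33 ± 0.11. DNA damage response genes had 7 higher, 1 lower and 2 not called of 10 (8 and 1 adjusted over the list alone, adjusted p = 0.047, and adjusted p = 0.26 with an estimated correlation). The list did not pass with library totals (camera, adjusted p = 0.057) or with the replicate number as a block. NAC044 rose by 3.00 ± 0.25. Ribosomal proteins had 99 higher, 34 lower and 182 not called of 315 (87 and 30 adjusted over the list alone, adjusted p = 0.0081, and adjusted p = 0.74 with an estimated correlation) and a median of 0.09. Proteasome subunits had 39 higher of 44 and a median of 0.93, and 28 of 30 heat shock genes were higher (adjusted p = 5.4e-15 and 5.7e-14; adjusted p = 0.1 and 0.26 with an estimated correlation). In all 19 of 40 lists passed at 24 h with the preset correlation and 0 with an estimated correlation, where camera gave 11 an unadjusted p under 0.05.

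Calls at 1.5 and 6 h overlapped more than those of either time with 24 h. The genes higher at both 1.5 and 6 h numbered 4809 (2136.3 expected of independent lists) and those lower at both 5028 (2508.9 expected), with 270 and 584 called in opposite directions. Between 1.5 and 24 h 2702 were higher at both and 3550 lower at both (1756 and 2432.2 expected), and between 6 and 24 h 3522 and 4287 (2088.7 and 2705.3 expected). Across genes, which are not independent replicates, Pearson's r of the changes was 0.81 between 1.5 and 6 h, 0.42 between 1.5 and 24 h and 0.60 between 6 and 24 h. These 3 comparisons share no library.

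Whether the As(V) effect itself differed between times was tested as an interaction. From 1.5 to 6 h the effect was higher for 5212 genes and lower for 3497, from 6 to 24 h 5311 and 7002, and from 1.5 to 24 h 5521 and 6399. With library totals those counts were 2674 and 7738, 12353 and 2640, and 10329 and 3311 (25.7%, 82.4% and 75.7% higher, against 59.8%, 43.1% and 46.3%). The median change of all genes moved in these from 0.01 to -0.40, from -0.06 to 0.95 and from -0.03 to 0.58. GSTU12, a glutathione transferase, had the effect change by -6.29 ± 0.74 from 1.5 to 6 h, as did the lipase DLAH by -6.68 ± 0.90 and PP2-B13 by -6.66 ± 0.66 (largest adjusted p = 0.00016). The effect rose most in AT2G37480 at 7.10 ± 2.11, AT3G04854 at 6.30 ± 1.62 and AT2G47844 at 5.79 ± 1.92 (adjusted p = 0.026, 0.0083 and 0.03), calls lost in 7, 1 and 8 of 20 alternatives.

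For AT5G64401 the size of the effect at 6 h is uncertain. From 6 to 24 h the effect fell most in AT5G64401 at -7.83 ± 0.99, AT5G65609 at -7.00 ± 1.24 and the WRKY gene ABO3 at -6.18 ± 1.44 (adjusted p = 3.7e-05, 0.00074 and 0.0032). It rose most in the peroxidase AT2G41480 at 5.65 ± 0.91, in AT1G48750 and in the potassium transporter AT3G56290 at 4.93 ± 0.69; the value of AT1G48750, 5.50 ± 0.61, rests on the pseudocount because the gene was listed at 0 at 6 h of As(V). From 1.5 to 24 h it fell most in the indole glucosinolate methyltransferase IGMT4 at -7.62 ± 1.35, AT1G65484 at -7.39 ± 1.78 and AT1G05575 at -7.37 ± 0.50, and rose most in AT2G47844 at 8.18 ± 1.75, the glycosyltransferase AT2G22590 at 6.55 ± 0.57 and AT3G56290 at 6.06 ± 0.49 (largest adjusted p = 0.0045). Lists past the threshold numbered 12, 14 and 18 in these comparisons and 0 in each with an estimated correlation, where camera gave 0, 2 and 1 an unadjusted p under 0.05. Phosphate starvation genes had effects that differed by a median of -1.87 from 1.5 to 24 h, or -1.45 with library totals (3 higher, 25 lower and 4 not called of 32; camera, adjusted p = 6.7e-06, and adjusted p = 0.4 with an estimated correlation), and phenylpropanoid and flavonoid genes by 2.97, or 3.69 with library totals (9 higher and 2 not called of 11; adjusted p = 0.00032, and adjusted p = 0.4 with an estimated correlation).

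The mock libraries show what changed over time in phosphate-free liquid medium without As(V). Time in this medium and time of day cannot be told apart in these comparisons. Phosphate starvation genes rose from 1.5 to 24 h, with 29 higher and 3 lower of 32 (29 and 3 adjusted over the list alone) and a median of 1.47 (camera, adjusted p = 7.5e-24, and adjusted p = 0.19 with an estimated correlation). KIN1, a gene of cold and abscisic acid responses, fell from 673 ± 97.0 to 25.7 ± 2.82 FPKM (-4.65 ± 0.22, adjusted p = 4.6e-07). ARD3 rose by 4.95 ± 0.75 and AT1G19960 by 4.49 ± 0.38, as did AT1G65484 at 4.47 ± 1.31 (adjusted p = 0.032), a call lost in 4 of 17 alternatives, while CYP94B1 changed by -3.85 ± 0.24 and AT1G62975 by -3.83 ± 0.29. From 1.5 to 24 h 2464 genes rose and 2333 fell, or 24.3% of those tested.

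From 1.5 to 6 h in mock 1863 genes rose and 2312 fell, or 21.1%; with library totals the split was 2707 and 1921 (58.5% higher, against 44.6%). RNS1, a ribonuclease of phosphate starvation, fell from 87.8 ± 27.1 to 3.66 ± 0.876 FPKM (-4.24 ± 0.40, adjusted p = 8e-05), and AT5G64401 and AT4G25433 by -4.28 ± 0.93 and -3.63 ± 0.61. The genes that rose most were ERF13 at 2.58 ± 0.30, DLAH at 2.53 ± 0.36 and RTFL7 at 2.60 ± 0.70, the last a call lost in 4 of 15 alternatives. Ribosomal proteins had 154 higher, 3 lower and 158 not called of 315 (191 and 7 adjusted over the list alone, camera, adjusted p = 3.2e-18, and adjusted p = 0.37 with an estimated correlation). The counts called in mock moved by over 1.5 times when a library was left out: without replicate 2 of the mock at 6 h 833 genes rose and 1183 fell from 1.5 to 6 h, and without replicate 1 of the mock at 1.5 h 1573 rose from 1.5 to 24 h. Lists past the threshold numbered 16 from 1.5 to 6 h and 13 from 1.5 to 24 h, and 0 in both with an estimated correlation, where camera gave 5 and 2 an unadjusted p under 0.05.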

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

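All tests of explanations in this part were chosen only after the result was seen, except the comparison of phosphate starvation genes with the start, which was written before.

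Genes changed in both directions at 6 h of As(V), 7089 higher and 7429 lower. With library totals 3266 genes were still higher, so these calls did not come from the deposited scaling alone. As deposited, 4340 genes were higher by at least 1 (log2), and library totals moved the median of all genes from -0.12 to -1.04. This test could therefore hardly have come out otherwise. The numbers higher and lower both remain tied to the scaling, since the other higher calls were lost and 2292 of them were called lower. The top genes of each library held a minority of its reads, so a few genes did not take most of them. Without the 141 top genes the ratio of scaling size to reads lay at -1.07 (log2, As(V) minus mock, SD 0.023 within groups), against -1.21 with them. With such a minority removed, this ratio could hardly have come near mock, so no conclusion is drawn from it. Whether many higher genes together took the reads was not tested. A difference in depth is argued against by estimated reads at 0.94 of mock. It stays open whether the total messenger RNA per root changed, which these data could not show.

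Phosphate starvation genes were lower with As(V) at 24 h, with a median of -1.90. With library totals the median was -1.81. The scalings differ little at 24 h, with a median change of all genes of -0.06 as deposited and 0.03 with library totals. This test could therefore hardly have come out otherwise. Mock levels rose over the same time, so the lower level may be a missing rise rather than a fall: As(V) at 24 h against mock at 1.5 h had a median of -0.47 (3 higher and 20 lower of 32, from -4.55 to 1.08). A missing rise alone is argued against for the 20 members called lower than mock at 1.5 h. For the list as a whole the explanations cannot be told apart, because that median lies near the limit of 0.5 although 20 members were lower. By the rule written before, a median within the limit of 0.5 went with a missing rise, and -0.47 met it. The verdict was made stricter after the value was seen.

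Root hair genes fell at 6 h with a median of -1.71. A uniform loss of root hair cells is argued against by 17 of 33 members lying more than 1 (log2) and 3 SE from the median, only 1 above the bound of 16 set for this test. Members ran from -4.43 to 3.49. This test replaced a first one after its values, 9 members higher as deposited and 3 with library totals, had been seen. A loss of hair cells, alone or together with other changes, stays open.

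Of 34 genes looked at, 26 had As(V) effects that differed between times by the interaction test (limma, adjusted p under 0.05), each given as the later minus the earlier effect, with the value from library totals in brackets. Each gene is shown at the interval with its lowest adjusted p, and most were picked for extreme effects in these same libraries. Of all genes tested, 44% were called from 1.5 to 6 h, 62.3% from 6 to 24 h and 60.3% from 1.5 to 24 h. The count of 26 therefore does not set these genes apart. All 26 were also called with library totals, although several values were much smaller. From 6 to 24 h ASK18 differed by -4.08 (-2.78), WRKY6 by -2.94 (-1.64), AT2G21045 by -1.59 (-0.28), GSH1 by -2.00 (-0.69), UGT74E2 by -3.88 (-2.59) and AT5G64401 by -7.83 (-6.55). GL2 differed by 0.66 (1.56), PHT1;4 by 1.57 (2.78), AT1G34510 by 3.09 (3.46), XTH31 by 3.76 (4.59) and AT5G04960 by 3.32 (4.1) over the same interval. AT1G68238 differed by 4.39 (4.55), a value that depends on the pseudocount because the gene was listed at 0 at 6 h of As(V).

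From 1.5 to 24 h Hsp70b differed by -1.52 (-0.78), AT1G52560 by -2.73 (-1.99), AT5G44070 by -4.66 (-3.94), AT5G14650 by -4.95 (-4.34) and AT5G15180 by -3.66 (-3.03). AT1G19900 differed by 2.95 (3.39), UGT84A1 by 5.67 (6.13), TT7 by 4.02 (4.5), XTH13 by 2.84 (3.32) and PHT1;1 by 1.08 (1.81). AT1G48750 differed by 2.30 (2.94); its value at 6 h depends on the pseudocount. From 1.5 to 6 h ANL2 differed by 1.69 (1.09), SPX1 by -2.36 (-2.92) and AT5G46900 by -3.42 (-3.63).

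Of 40 lists, 25 had effects that differed between times by camera with the preset correlation, and none did with an estimated correlation. Each list is shown at the interval with its lowest adjusted p. The size of many of these differences depended on the scaling, so each median difference is followed by its value with library totals in brackets. From 1.5 to 24 h it was -1.87 (-1.45) for phosphate starvation, -2.16 (-1.45) for mitochondrial stress, -1.13 (-0.44) for suberin and -1.26 (-0.55) for aquaporins. It was -2.49 (-2.06) for camalexin and indole metabolism, -1.53 (-0.80) for xyloglucan endotransglucosylases, -0.93 (-0.21) for extensins, 2.97 (3.69) for phenylpropanoid and flavonoid genes and 0.45 (1.17) for proteasome subunits.

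From 6 to 24 h the median difference, with library totals in brackets, was -2.00 (-0.69) for sulfate assimilation and glutathione, -2.14 (-0.87) for glutathione transferases, -3.38 (-2.12) for xenobiotic detoxification and -2.00 (-0.69) for heat shock genes. It was -1.25 (-0.27) for jasmonate and -1.14 (-0.19) for WRKY factors, whose calls went from 3 higher and 36 lower to 14 and 22. Reactive oxygen scavenging changed sign, from -1.16 to 0.15 with library totals. Endodermis and Casparian strip genes had 1.06 (2.03), DNA damage response 0.89 (1.73) and auxin 0.99 (1.95). From 1.5 to 6 h it was -0.84 (-1.18) for cell cycle and DNA replication, 0.81 (0.23) for abscisic acid, 1.50 (1.3) for the circadian clock, -0.49 (-0.99) for class III peroxidases and -0.11 (-0.67) for ribosomal proteins. NAC factors changed sign, from 0.37 to -0.07 with library totals.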

How the results depend on the processing

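All alternatives here were chosen before the data were examined, except voom on the estimated reads, the pseudocounts, no minimum of reads and the fit without the 6 h libraries, which were chosen only after the result was seen. The cause was not tested for any difference below.

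With library totals only, genes higher and lower with As(V) numbered 3057 and 12309 at 1.5 h and 3266 and 13770 at 6 h. The effects compared gave 2674 and 7738 from 1.5 to 6 h, 12353 and 2640 from 6 to 24 h, and 10329 and 3311 from 1.5 to 24 h. AT2G21045 at 1.5 h went to -0.52 and LHCA1 at 6 h to -0.35 with library totals, both reversed. Lists passed that had not before: ethylene (adjusted p = 0.036), camalexin (0.016) and ERF and AP2 factors at 1.5 h, abscisic acid (0.037) and ribosomal proteins (7e-05) at 6 h, and jasmonate (0.034) at 24 h. Lists no longer passed with library totals were cytochromes P450 (0.36), expansins (0.17), ribosomal proteins (0.094) and proteasome subunits (0.14) at 1.5 h. At 6 h they were reactive oxygen scavenging (0.35), xylem and phloem (0.051), cell cycle and DNA replication (0.074), auxin (0.15), cytochromes P450 (0.85), xyloglucan endotransglucosylases (0.35) and leucine-rich repeat receptor kinases (0.17). At 24 h they were DNA damage response (0.057) and the circadian clock (0.051).

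With a log2 change of at least 1 required, genes higher and lower were 2792 and 2880 at 1.5 h, 4340 and 4019 at 6 h, and 1460 and 2896 at 24 h. The effects compared gave 2702 and 1447, 2687 and 4602, and 2559 and 3754, in the order above. The mock comparisons gave 173 and 350 from 1.5 to 6 h and 509 and 424 from 1.5 to 24 h. By construction such counts are smaller.

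With limma-trend without precision weights 1177 genes rose in mock from 1.5 to 6 h, against 1863. Leaving out a library, with the lone sample of its group assumed to vary like the others, gave 833 to 1061 higher: 1061 without replicate 1 and 872 without replicate 2 of mock at 1.5 h, and 879 and 833 without replicates 1 and 2 of mock at 6 h. Those lower were 1784 without replicate 1 and 1493 without replicate 2 of mock at 1.5 h, and 1287 and 1183 without replicates 1 and 2 of mock at 6 h. From 1.5 to 24 h in mock 1573 rose without replicate 1 of mock at 1.5 h, the least, and 2172 without replicate 1 of mock at 24 h, the most, against 2464.

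With an estimated correlation, camera passed 0 lists at 1.5 h, 0 at 6 h, 0 at 24 h, 0, 0 and 0 in the effects compared, and 0 and 0 in mock. Unadjusted p lay under 0.05 for 4, 4, 11, 0, 2, 1, 5 and 2 lists, and the lowest adjusted p was 0.22, 0.29, 0.1, 0.63, 0.57, 0.4, 0.31 and 0.19.

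With the replicate number as a block, genes higher and lower were 5996 and 6758 at 1.5 h, 7119 and 7483 at 6 h, and 5848 and 7246 at 24 h, and 19, 23 and 18 lists passed, DNA damage response at 24 h no longer among them. Differences between replicates correlated at -0.07 to 0.11 between groups, so the numbers did not pair the libraries.

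All other counts stayed within 1.5 times. The DESeq2 Wald test was not run, because the values are not counts.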

Other observations

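In this part the values of untested genes and the comparisons of other pairs of groups were chosen only after the result was seen.

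Vacuolar ABC transporters of arsenic handling were higher with As(V) at 1.5 and 6 h. ABCC1 was at 2.16, 3.54 and -0.28 (log2, As(V) over mock) at 1.5, 6 and 24 h, ABCC2 at 2.24, 4.13 and 0.91 and ABCC3 at 2.34, 5.37 and 2.1 (largest SE 0.12, largest adjusted p = 0.0021), whereas NIP5;1, a channel of boric acid that also passes arsenite, was at -2.42, -1.25 and -0.06. BTS, an E3 ligase that restrains the iron response, rose to 388 ± 9.89 FPKM at 6 h from 13.1 ± 1.32 in mock (4.80 ± 0.09, limma, adjusted p = 5.2e-12), and ABCG37, an exporter of iron-chelating coumarins, rose by 3.86 ± 0.09. SMR5, an inhibitor of the cell cycle, rose by 4.87 ± 0.31 at 1.5 h, 5.61 ± 0.32 at 6 h and 1.38 ± 0.30 at 24 h.

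WRKY38 and WRKY62, factors of salicylic acid defence, fell at 24 h by -4.28 ± 0.33 and -4.11 ± 0.60, while WRKY6 was higher. RSL2, a regulator of root hair growth, fell from 28.9 ± 1.37 to 1.1 ± 0.245 FPKM at 24 h (-3.85 ± 0.23), and MYC1, a partner of epidermal MYB factors, by -1.87 ± 0.17.

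Against mock at 1.5 h, the As(V) libraries of 24 h had 27 of 30 heat shock genes higher and 1 lower (median 3.72), 1 of 33 root hair genes higher and 29 lower (-1.18), 40 of 44 proteasome genes higher and 0 lower (0.92), and 1 of 18 aquaporins higher and 16 lower (-2.19). Against As(V) at 1.5 h, they had 11 of 32 phosphate starvation genes higher and 15 lower (-0.22), 0 of 30 heat shock genes higher and 28 lower (-3.08), and 2 of 18 aquaporins higher and 13 lower (-1.38). In the same comparison 30 of 44 proteasome genes were higher and 3 lower (0.39), and 10 of 33 root hair genes were higher and 13 lower (0.15).

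Some abundant genes were left out of the test by its filter, because no reads or too few were estimated. The metallothionein MT1A lay at 15800 to 22400 FPKM in mock, 19900 and 20200 at 1.5 h of As(V), 23800 and 38700 at 6 h, and 10500 and 12100 at 24 h. AT5G41992 was at 1430 and 1260 FPKM at 6 h of As(V) and 71.5 and 73.4 in mock, AT1G36732 at 766 and 724 against 81.1 and 79.7, and AT1G70782 at 733 and 668 against 128 and 131. No test was made of these.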
